A study of Arabidopsis thaliana with 8 samples.

How the data were processed

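RNA was measured in 8 samples of guard cell protoplasts of Arabidopsis thaliana, 4 from wild-type Col-0 (WT) and 4 from the scap1 mutant, each on 1 array of an Agilent 4-pack slide (design 021169). Per the labels' protocols, plants were grown for 4 weeks in continuous light, leaves were blended and digested with enzymes, mesophyll cells were removed on a density gradient, RNA was extracted independently for each replicate, and the labelled RNA carried Cy3. Groups and replicate numbers were taken from the sample titles. The number of arrays limits the precision of all values.

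The scanner files hold spot intensity in arbitrary units on a linear scale, 1 array per file, per the file headers. The authors ran Agilent Feature Extraction, version 10.1.1.1 on the arrays of slide 1 and version 10.7.3.1 on those of slides 2 and 3, per the file headers, with background subtraction, spatial and multiplicative detrending, and surrogates for signals at or below noise. Normalization between arrays is not part of these processed intensities, per the file headers. The deposited value table also holds intensity. Set against the scanner values, each of its columns was the processed signal divided by 1 factor for the array, on a linear scale, not centred by gene and in the same direction as the signal, with a floor of 0.01 for replicates 1 and 2 and of 0.002 for replicates 3 and 4. Its column medians were 0.138, 0.118, 0.129 and 0.143 for WT replicates 1 to 4 and 0.123, 0.113, 0.111 and 0.115 for scap1 replicates 1 to 4. How the factor was chosen is not given in the sources used here. The table covers 43553 of the 43603 probes and served as an alternative.

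For the main values, spots of control type were left out, spots of 1 probe were averaged, and 60 probe values whose spots were outliers in the feature extraction were left out. The log2 of the processed signal minus the log2 of the array's 75th percentile was taken. That percentile was 1500, 1730, 1475 and 1491 on WT replicates 1 to 4 and 1810, 1840, 1319 and 1445 on scap1 replicates 1 to 4, and 79.2, 71.9, 71.8 and 73.8% of the spots on the WT arrays and 72.8, 64.5, 70.7 and 71.9% on the scap1 arrays were well above background. Probes were named through the accession in the files, matched without version to a table of the assembly TAIR10.1 that was used for names only, or through a locus ID in the file. Of the 43603 probes, 36498 had 1 locus (34267 by accession, 325 by a list of accessions and 1906 by the locus in the file), 15 had several and 7090 had none, and probes with several loci or none were kept out of the main fit. The named probes covered 26430 loci, of which 7693 had several probes, and the probe with the highest mean over all arrays stood for its gene. Coordinates are those of the files, build ath1:Jan2004. Genes of the fixed lists whose symbol is absent from the reference table carry the symbol of the list, and this holds for PME6, CBC1 and PATROL1 among the genes discussed.

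A gene was tested when its probe was well above background on at least 4 of the 8 arrays, which left 20360 genes. The test was limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p here comes from limma. A gene that was not well above background on any array of 1 group has only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal of any single spot well above background. SCAP1 was also tested with an exact two-sided permutation test. Gene lists were tested with limma's camera (inter-gene correlation preset at 0.01, and again estimated), and with fry, with Benjamini-Hochberg adjustment over the 19 lists, which hold 438 locus IDs. The lists were guard cell ion transport, stomatal development, abscisic acid signalling, carbon dioxide and light signalling, abscisic acid and dehydration response, cell wall, cuticle and wax, starch, sugar and malate metabolism, photosynthesis, epidermis and trichome markers, vascular markers, wounding, jasmonate and touch response, heat shock response, salicylic acid defence, circadian clock, flavonoid and anthocyanin synthesis, glucosinolate synthesis and breakdown, cell cycle, and DOF transcription factors. A last list of 3 genes (GORK, MYB60 and PME6), remembered from the study of these samples, gave values and no set test of its own. These genes are also members of the lists of ion transport, stomatal development and cell wall, and count in the tests of those lists. The groups, the lists, the main test, the rule for named genes and the alternatives, apart from those stated as added, were fixed before the data were examined. By that rule the text names SCAP1, the 15 genes higher and the 15 lower with the largest log2 fold change among those past the threshold with no overlap of the groups, and members of the lists, those past the threshold first (up to 4 per list). Members named beyond those 4, and members that did not pass, are named as examples.

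Slide and scan gave the same division of the arrays, and each slide held both groups. Slide, the replicate number and the version of the feature extraction were each fitted as a block. The replicate numbers, which come from the titles, paired the samples: deviations from the group means correlated across genes with r = 0.634, 0.583, 0.705 and 0.617 for numbers 1 to 4, and every array correlated best with its own number in the other group. For numbers 3 and 4 this cannot be told apart from the slide. Other alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter, a filter on all 8 arrays, the mean of all probes of a locus, trend and robust moderation, the value table, stricter thresholds and leaving out each array in turn. Chosen after the data were seen were a test of each probe singly, the arrays of slide 1 alone, those of slides 2 and 3 alone with slide as a block, and the estimated correlation with slide as a block. The fits were tested on simulated data with 200 changed genes among 20328 in 5 runs: the main model called 42.4 genes on average, 0.2 of them false, and recovered 0.2% of the 2-fold and 42% of the 4-fold changes, while slide as a block recovered 46.2 and 78.4%, with 5.6 false calls of 130. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.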

Results

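The series measured mRNA in guard cells, the paired cells that open and close the stomatal pore, of Arabidopsis thaliana. Guard cell protoplasts (cells freed of their walls by enzymes) were made from leaves of wild-type Col-0 plants (WT) and of the scap1 mutant, and RNA of each preparation was hybridised in 1 colour (Cy3) to an Agilent oligonucleotide array. There were 4 WT and 4 scap1 arrays, described in the labels as biological replicates, and the single comparison of the design was scap1 against WT. SCAP1 (AT5G65590) encodes a transcription factor of the DOF zinc finger family. The signal at the 75th percentile lay between 1319 and 1840 units per array, 64.5 to 79.2% of the spots were well above background, and no spot was saturated. The number of arrays limits the precision of every value. Replicates 1 and 2 of both groups shared slide 1, replicate 3 of both groups lay on slide 2 and replicate 4 of both groups on slide 3, so that every slide held both genotypes. Levels are log2 signals relative to the 75th percentile of each array.

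**Figure D1:**
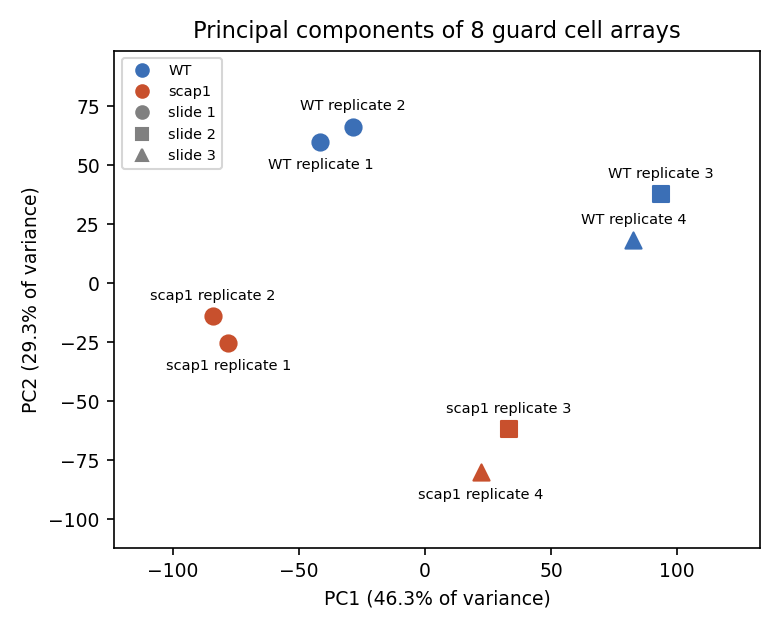
Principal components of the log2 levels of all genes tested, 1 point per array, with colour for genotype and shape for slide. The horizontal axis (PC1, 46.3% of the variance) parts slide 1 from slides 2 and 3, and along the vertical axis (PC2, 29.3%) the 4 WT arrays lie above 0 and the 4 scap1 arrays below 0.

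The mutated gene itself was measured on all 8 arrays. Its probe lies on chromosome 5 from 26212095 to 26212154 (build ath1:Jan2004, as in the scanner files). The labels do not say what the mutation is or whether the probe lies inside it, so that its level checks neither the labels nor the loss of function. SCAP1 mRNA was at 2.03 ± 0.61 in WT and 3.12 ± 1.13 in scap1 (log2 relative to the 75th percentile, SD, n = 4), a log2 fold change of 1.09 ± 0.56 (SE). This difference did not pass the threshold (limma, adjusted p = 0.310), and an exact two-sided permutation test over the 70 assignments of the arrays gave p = 0.171, where the smallest possible value was 0.0286. Both tests left out the pairing of the arrays by slide and replicate number. Within slides the log2 difference was 1.53 on slide 1, 0.83 on slide 2 and 0.45 on slide 3. With slide as a block the difference passed (limma, adjusted p = 0.0175), as it did with the replicate number as a block (adjusted p = 0.0335).

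Guard cell preparations of the mutant held less mRNA of several genes known for stomatal movement and more of a few others. GORK, the outward potassium channel that lets potassium leave closing guard cells, was 11.4-fold lower in scap1 (log2 fold change -3.51 ± 0.43, SE, 4 arrays per group). PYL2, an abscisic acid receptor, was lower by a log2 fold change of -3.70, BLUS1, a kinase of the blue light response of stomata, 9.95-fold lower, and MYB60, a transcription factor expressed in guard cells, 6.59-fold lower. PME6, a pectin methylesterase that acts on the cell wall, was 31.8-fold lower with the brighter of its probes (log2 fold change -4.99, against -2.38 with the other), and these could not be checked for transcripts of an overlapping gene. In the other direction, the vacuolar malate and anion transport genes ALMT6, TDT and ALMT9 rose, by log2 fold changes of 1.85, 1.7 and 0.81, as did SPCH and MUTE, transcription factors of the early stomatal lineage. The calls of ALMT6, SPCH and MUTE were lost in 5, 6 and 5 of the 8 fits that left out 1 array. Their log2 fold changes there ran from 1.6 to 2.11, 2.26 to 3.15 and 1.8 to 2.39. With slide as a block all of them passed (limma, adjusted p = 0.00169, 0.00257 and 0.0151). For TDT and ALMT9 no values of the fits with 1 array left out are given. With normexp background correction SPCH went from 2.77 to 1.74 and lost its call (adjusted p = 0.0606), and MUTE went from 2.06 to 0.97. GORK, MYB60 and PME6 were remembered from the study of these samples and are no independent evidence of its direction.

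**Figure D2:**
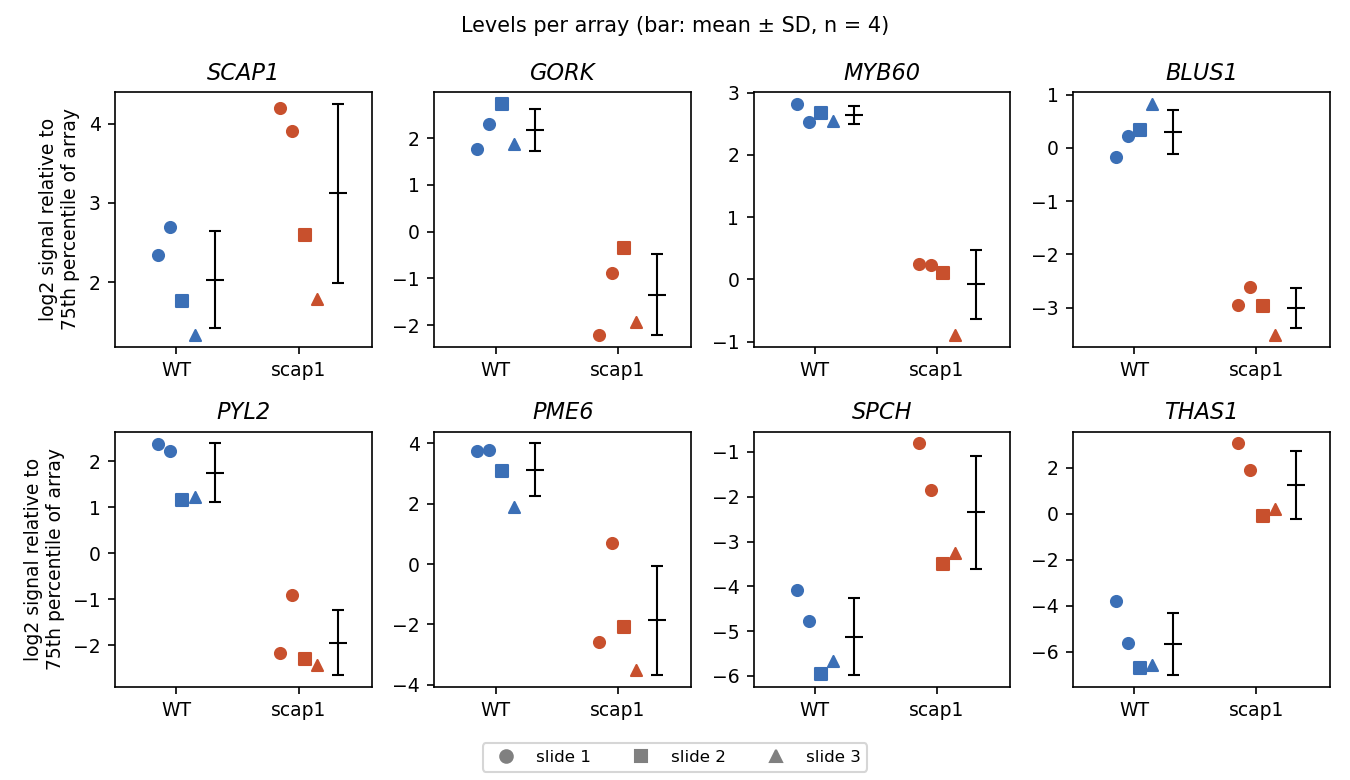
Level of 8 genes on each array (vertical axes, log2 signal relative to the array's 75th percentile, each with its own range), with shape for slide and a bar for the mean ± SD of 4 arrays. For every gene but SCAP1 the 4 scap1 arrays lie all below or all above the 4 WT arrays, for GORK with means of -1.35 and 2.17.

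Across all 20360 genes tested, 1172 differed between scap1 and WT at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 460 higher and 712 lower in scap1. Of these, 1046 differed at least 2-fold, and 141 rose and 248 fell at least 4-fold. In 1170 of the 1172 genes the groups did not overlap, and the sign of the difference was the same on all 3 slides in 1170. Since each slide held both groups, a lack of overlap fixes the sign on every slide, so that the latter count is no separate support. Over all genes tested, 3277 (16.1%) had groups that did not overlap, against 2.86% if all 70 assignments of the arrays were equally likely. Arrays were paired by slide and replicate number, which that share leaves out, so that it is only a rough guide. With slide as a block 5326 genes passed (2692 higher and 2634 lower), among them all 1172, and with the replicate number as a block 4522 passed (2319 higher and 2203 lower), among them 1167 of the 1172. Slide 1 alone gave 4401 genes, and slides 2 and 3 together, with slide as a block, gave 7891. These fits, of 2 arrays per group each, were added after the data were seen. On slide 1 the arrays of a group were close to each other (r = 0.988 for WT and 0.991 for scap1). The larger counts are thus no stronger evidence than the full fit. Log2 fold changes on slide 1 and on slides 2 and 3, which share no array, correlated across 20328 genes with r = 0.556 and rho = 0.453 (genes are not independent replicates). The share of higher calls, 39.2%, depended on the scaling, for it was 53.2% after quantile normalization and 62.7% after scaling to the median of each array, which moved the median log2 fold change of all genes to 0.19. Without WT replicate 2 the count was 748, without WT replicate 3 it was 560, without WT replicate 4 it was 732, and without scap1 replicates 1, 2 or 4 it was 536, 680 or 748.

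The genes that fell furthest in scap1 came from several kinds. AT5G25840, of unknown function, had a log2 fold change of -5.46 ± 0.73 (SE), from 2.22 ± 1.02 in WT to -3.24 ± 1.37 in scap1 (SD, n = 4; limma, adjusted p = 0.00564). AT1G29660, a lipase of the GDSL family, changed by -5.28 ± 0.71, and FUS3, a B3 transcription factor known as a regulator of seed maturation, by -5.06 ± 0.55. The germin-like genes AT5G39130, AT5G39160 and GER2 (AT5G39190), which are close relatives whose transcripts may share probes, had log2 fold changes of -5.21, -5.05 and -4.95. PME6 (AT1G23200) had a log2 fold change of -4.99 ± 0.85 with 1 of its probes and -2.38 with the other (-3.69 with their mean). FUM2, a cytosolic fumarase that makes fumarate from malate, changed by -4.63 ± 0.41, and RAB18, a dehydrin induced by abscisic acid, by -4.53 ± 0.73. AT5G66220, annotated as a chalcone isomerase, and AT5G14860, a glycosyltransferase, changed by -4.70 and -4.54, each well above background on 1 of the 4 scap1 arrays. AT1G22690, a gene annotated as responsive to gibberellin, and AT2G05540, a glycine-rich protein gene, fell 23.9-fold and 21.6-fold from WT levels of 4.77 ± 0.81 and 5.40 ± 0.28 (SD, n = 4). AT2G25150, a transferase, was not well above background on any scap1 array and was at least 6.97-fold lower there (limma, adjusted p = 0.00549), a bound taken from the WT mean and the lowest spot signal well above background on each scap1 array. Its fitted log2 fold change went from -4.79 to -1.46 with normexp background correction, where it missed the threshold (adjusted p = 0.051), to -3.21 with slide 1 alone and to -6.36 with slides 2 and 3 alone. Normexp also brought AT5G66220 to -2.06, AT5G14860 to -2.39, AT1G20470 to -3.56, FUS3 to -3.81, AT5G39160 to -4.32 and AT5G25840 to -4.82. The mean of its probes brought FUM2 to -3.85. With the arrays of slide 1 alone PME6 missed it (-4.68, adjusted p = 0.0614). AT1G20470, an auxin-responsive gene, had a log2 fold change of -4.69 ± 0.90 and missed the threshold without WT replicate 3 or without scap1 replicate 1, 2 or 3 (log2 fold changes from -5.25 to -3.93 over the 8 fits that left out 1 array).

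Among the genes that rose furthest, THAS1, the thalianol synthase that makes a root triterpene, rose 123-fold (log2 fold change 6.94 ± 0.85, SE; limma, adjusted p = 0.00379), from -5.68 ± 1.34 in WT, where 2 of 4 arrays were well above background, to 1.27 ± 1.48 in scap1 (SD, n = 4). PYK10, a beta-glucosidase abundant in root endoplasmic reticulum bodies, rose 60.7-fold (5.92 ± 0.53), and all 6 of its probes were higher, by 2.59 to 6.96 on the log2 scale. ENODL1, an early nodulin-like plastocyanin domain protein, changed by 5.85 ± 0.59, and PGSIP3, a glycosyltransferase of the cell wall that was well above background on 2 of the 4 WT arrays, by 5.51 ± 0.40. ZIP3, a zinc transporter, had a log2 fold change of 4.97 ± 0.46 and was well above background on 1 of the 4 WT arrays. BCAT7, a branched-chain aminotransferase, changed by 4.49 ± 0.58. The B3 family gene AT3G46770 and the MADS-box gene AT1G17310 were not well above background on any WT array, and were at least 9.17-fold and at least 12.4-fold higher in scap1 (limma, adjusted p = 0.00271 and 0.00618). The remaining genes of this group were AT5G50830, AT3G24790 (a protein kinase), AT3G59710 (a short-chain dehydrogenase), AT1G03020 (a glutaredoxin), AT4G04460 (an aspartyl protease), AT4G12050 (a DNA-binding protein) and AT5G50090, with log2 fold changes from 4.48 to 5.12. Of these, AT5G50830, AT1G03020 and AT4G04460 were well above background on 3 of the 4 WT arrays and AT3G59710 on 1. Normexp background correction moved 31 named genes by more than 1.5-fold, each towards 0, among them THAS1 (to 5.13), ENODL1 (5.07), PYK10 (4.43), BCAT7 (3.21), PGSIP3 (2.90), ZIP3 (2.42), AT1G17310 (1.87) and AT3G46770 (1.43). The offset of 50 that it adds to each signal draws ratios of low signals towards 0 by itself. That direction was thus largely set by the method, here and for the other genes given with normexp. Normexp brought the 7 remaining genes of this group to between 2.19 (AT3G59710) and 3.98 (AT3G24790). The mean of their probes brought PYK10 to 5.15 and AT4G12050 to 3.05, and slide 1 alone moved 17 named genes by more than 1.5-fold. All 67 named genes other than SCAP1 passed with slide as a block (adjusted p from 0.000669 to 0.0243) and had the same sign on all 3 slides. Neither is added support for these genes. Their groups did not overlap, which fixes the sign on each slide, and all 1172 genes past the threshold also passed with slide as a block.

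Among 19 gene lists fixed before the data were examined, camera with a preset inter-gene correlation of 0.01 placed 6 lower and 2 higher in scap1 than the remaining genes. None of these 8 calls held with an estimated correlation, and their adjusted p then lay between 0.145 and 0.643. Limma's fry, which compares no list with other genes, found change in either direction in 13 of the 19 lists and in all 19 with slide as a block. It found change in 1 direction on balance in 5 lists (carbon dioxide and light signalling, abscisic acid and dehydration response, circadian clock, flavonoid synthesis and cell cycle), and with slide as a block in 6, the epidermis list added. More members of the lists passed singly with slide as a block, where 26.2% of all genes tested passed. The counts that follow are to be read against that share and were not tested against it. There were 9 higher and 5 lower for ion transport, 8 and 4 for stomatal development, 2 and 1 for abscisic acid signalling, 0 and 6 for carbon dioxide and light signalling, and 1 and 8 for abscisic acid response. There were 8 and 5 for cell wall, 1 and 7 for cuticle, 5 and 7 for starch, sugar and malate, 0 and 12 for photosynthesis, 2 and 5 for epidermis and 1 and 0 for vascular markers. There were 6 and 6 for wounding, 1 and 0 for heat shock, 7 and 1 for salicylic acid defence, 0 and 3 for the clock, 0 and 5 for flavonoids, 2 and 1 for glucosinolates, 0 and 9 for cell cycle and 5 and 0 for DOF genes. Photosynthesis genes that are abundant in mesophyll, a cell type the preparation could hold and that guard cells share in part, had a median log2 fold change of -0.69 over 33 members (adjusted p = 0.00015 by limma's camera, and adjusted p = 0.643 with an estimated correlation). Fry passed neither for 1 direction (adjusted p = 0.166) nor for either direction (adjusted p = 0.0839). Within slides the median was -0.24 on slide 1, -0.87 on slide 2 and -1.41 on slide 3, and the call held with slide as a block (adjusted p = 1.34e-05), but not with the arrays of slide 1 alone (adjusted p = 0.105). Of the 33 members, 1 fell and none rose over all genes tested, and 3 fell adjusted over the list alone. The member that fell was PRK, the Calvin cycle phosphoribulokinase (log2 fold change -1.80 ± 0.43, with its 4 probes from -2.44 to 0.31). Of the 8 fits that left out 1 array (log2 fold changes from -2.06 to -1.46), PRK passed only in that without WT replicate 2. It also missed the threshold with normexp background correction, quantile normalization, no filter or the mean of its probes (adjusted p from 0.0509 to 0.0827). RBCS1A, a Rubisco small subunit, had -0.59 ± 0.49 and LHCB1.1, a chlorophyll-binding antenna protein, -0.73 ± 0.33, and neither passed. Vascular markers had a median of 0.49 over 10 members and did not pass (adjusted p = 0.0583, and adjusted p = 0.701 with an estimated correlation). The phloem factor APL rose (1.24 ± 0.23; 1 of 10 members over all genes tested and adjusted over the list alone). It lost its call without WT replicate 3 or scap1 replicate 1 (1.1 to 1.33 over the fits that left out 1 array) and with the mean of its probes (adjusted p = 0.0728). The vascular list passed with the replicate number as a block (adjusted p = 0.026), without WT replicate 4 (adjusted p = 0.00375) and without scap1 replicate 2 (adjusted p = 0.0156). It also passed with the mean of all probes of a locus (adjusted p = 0.0297) and with no filter (adjusted p = 0.0451). Its slide medians were 0.64, 0.46 and 0.21 (adjusted p = 0.0994 with slide as a block).

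Of 14 genes of carbon dioxide and light signalling in guard cells, 4 fell in scap1 and 10 did not pass, 3 of them above 0 (PATROL1 0.19, CA4 0.20 and CIPK23 0.37). The median of the list was -0.56 (camera, adjusted p = 0.00307, and adjusted p = 0.155 with an estimated correlation, or 0.421 with slide as a block as well). The kinases BLUS1 (log2 fold change -3.31 ± 0.28), CBC1 (-2.59 ± 0.49) and HT1 (-1.76 ± 0.20) and the blue light receptor PHOT1 (-1.88 ± 0.42) were those that fell, also adjusted over the list alone. HT1 went from 3.50 ± 0.21 to 1.74 ± 0.26 (SD, n = 4), and BLUS1 and HT1 kept their calls in every fit that left out 1 array. CBC1 lost its call without WT replicate 3 or 4 or scap1 replicate 1, 3 or 4 (-2.90 to -2.28 over these fits). PHOT1 lost it in each such fit except that without WT replicate 1 (-2.20 to -1.59), as well as with no filter (adjusted p = 0.0629) and with slide 1 alone (-1.15, adjusted p = 0.0541). On slide 1 alone CBC1 was at -1.39, and on slides 2 and 3 alone CBC1 was at -3.78 and PHOT1 at -2.61. The slide medians of the list were -0.50, -0.85 and -1.11, and camera passed with slide as a block (adjusted p = 0.0157) but not with the arrays of slide 1 alone (adjusted p = 0.0699). The photosynthesis list, with its median of -0.69, was lower on the same arrays.

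Guard cell ion transport genes went both ways. GORK, ALMT12 (an anion channel of stomatal closure, -2.59 ± 0.59) and CAX1 (a vacuolar calcium exchanger, -2.10 ± 0.40) fell. ALMT6 (a vacuolar malate channel, 1.85 ± 0.37), TDT (the vacuolar malate carrier, 1.7 ± 0.33) and ALMT9 (a vacuolar anion channel, 0.81 ± 0.18) rose. The other 28 of the 34 members did not pass, among them KAT1, an inward potassium channel (-1.61 ± 0.39, adjusted p = 0.0505, and 0.0173 with slide as a block), and SLAC1, the slow anion channel (-0.53 ± 0.32, adjusted p = 0.399). Adjusted over the list alone, 3 members rose and 4 fell. Among the fits that left out 1 array, ALMT12 lost its call without WT replicate 3 or 4 or scap1 replicate 1, 2 or 4 (-2.95 to -2.21 over the 8 fits) and with no filter (adjusted p = 0.0622). CAX1 lost it without WT replicate 3 or 4 or scap1 replicate 3 (-2.32 to -1.74), and ALMT6 without WT replicate 3 or 4 or scap1 replicate 1, 2 or 3 (1.6 to 2.11). On slide 1 alone ALMT12 and CAX1 were at -1.72 and -1.16, and on slides 2 and 3 alone at -3.46 and -3.05. As a set the list did not pass (median 0.33, mean -0.01, so that the mean differed in sign from the median and the test; camera in the upward direction, adjusted p = 0.488, and adjusted p = 0.800 with an estimated correlation). Limma's fry found change in either direction (adjusted p = 0.000143). Its slide medians were 0.14, 0.17 and 0.05, and it did not pass with slide as a block (adjusted p = 0.333).

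Stomatal development genes also moved apart. SPCH (2.77 ± 0.65), MUTE (2.06 ± 0.43) and the receptor kinase gene ERL1 (1.99 ± 0.38), all of low signal, rose, and MYB60 (-2.72 ± 0.28) fell from 2.64 ± 0.14 to -0.08 ± 0.55 (SD, n = 4). The other 20 of 24 members did not pass, among them FAMA, a transcription factor of guard cell identity (0.67 ± 0.67). FAMA was higher on every slide (0.64, 0.79 and 0.63) and passed with slide as a block (adjusted p = 0.0134). EPF1, a peptide signal of the lineage (-2.91 ± 0.90, adjusted p = 0.0995), and SDD1, a protease of the lineage (-1.93 ± 0.51, adjusted p = 0.0646), also passed with slide as a block (0.00128 and 0.0427) or over the list alone. The other alternatives are not given for EPF1 and SDD1. Adjusted over the list alone, 3 rose and 3 fell. SPCH missed the threshold without WT replicate 2, 3 or 4 or scap1 replicate 1, 2 or 4 (2.26 to 3.15 over the 8 fits that left out 1 array). MUTE, well above background on 3 of the 4 WT arrays, missed it without WT replicate 2, 3 or 4 or scap1 replicate 1 or 3 (1.80 to 2.39), and ERL1 without WT replicate 2 or 4 or scap1 replicate 1 or 3 (1.80 to 2.32). MYB60 kept its call in all 8 fits. SPCH also missed the threshold with normexp background correction (1.74, adjusted p = 0.0606) and no filter (adjusted p = 0.0715), and MUTE with slide 1 alone (1.65, adjusted p = 0.102). MUTE kept its call with normexp background correction, at 0.97. The median of the list was -0.03, but 0.12 after quantile normalization and 0.17 after median scaling, and the mean was 0.07 (camera in the upward direction, adjusted p = 0.663, and adjusted p = 0.800 with an estimated correlation; fry in either direction, adjusted p = 0.000104). Slide medians were -0.28, 0.50 and 0.36, and the adjusted p with slide as a block was 0.530. Cell cycle genes were lower (median -0.82 over 16 members; camera, adjusted p = 0.000409, and adjusted p = 0.155 with an estimated correlation). The mitotic cyclin CYCB1;2 (-1.58 ± 0.30), the kinase CDKB2;1 (-1.27 ± 0.26) and the cyclin CYCA1;1 (-1.03 ± 0.18) fell, and adjusted over the list alone 5 fell. With 1 array left out, CYCB1;2 lost its call without WT replicate 2 or 3 or scap1 replicate 1, 2 or 3 (-1.87 to -1.43) and CDKB2;1 without WT replicate 1, 2 or 3 or scap1 replicate 1, 2 or 3 (-1.43 to -1.14). CYCA1;1, well above background on 3 of the 4 scap1 arrays, lost it without scap1 replicate 1 (-1.12 to -0.95). All 3 also missed the threshold with normexp background correction and with quantile normalization (adjusted p from 0.0519 to 0.247). Their log2 fold changes were then -0.81, -0.64 and -0.37 with normexp and -1.35, -1.06 and -0.77 with quantile normalization. CDKB2;1 and CYCA1;1 missed it with median scaling (0.0614 and 0.0562) and CYCA1;1 with trend and robust moderation (0.0689). CDKB2;1 also missed it on slides 2 and 3 alone, with slide as a block (-0.96, adjusted p = 0.0724). The slide medians of the cell cycle list were -1.04, -0.79 and -0.48, and it passed with slide as a block (adjusted p = 0.000179). Photosynthesis genes were lower on the same arrays (median -0.69).

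Of 22 genes that abscisic acid and water loss induce, 2 fell, and the median was -0.50 (camera, adjusted p = 0.0136, and adjusted p = 0.170 with an estimated correlation, or 0.515 with slide as a block as well). RAB18 fell 23.1-fold and the late embryogenesis abundant gene LEA4-5 fell 5.78-fold (-2.53 ± 0.25), also adjusted over the list alone, while the other 20 did not pass, among them RD29A (-0.91 ± 0.39, adjusted p = 0.225, and 0.0427 with slide as a block) and NCED3, an enzyme of abscisic acid synthesis (0.25 ± 0.33). Slide medians were -0.47, -0.69 and -0.20, and camera's call held with slide as a block (adjusted p = 0.0132) but not with the arrays of slide 1 alone (adjusted p = 0.053). Photosynthesis genes were lower on the same arrays (median -0.69). Of the 29 abscisic acid signalling genes measured, PYL2 fell (-3.70 ± 0.42, also adjusted over the list alone) and the other 28 did not pass, among them the kinase OST1 (-0.05 ± 0.23). That list had a median of -0.05, but 0.15 after median scaling (camera, adjusted p = 0.617, and adjusted p = 0.706 with an estimated correlation), slide medians of -0.19, 0.01 and 0.15, and an adjusted p of 0.572 with slide as a block.

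Flavonoid synthesis genes had the largest shift of the 19 lists, with a median of -1.97 over 8 members (camera, adjusted p = 0.000409, and adjusted p = 0.145 with an estimated correlation). The glycosyltransferase UF3GT (-3.20 ± 0.28), the chalcone isomerase CHI (-2.55 ± 0.36) and the flavonol synthase FLS1 (-2.21 ± 0.46) fell, and 6 members fell adjusted over the list alone. UF3GT was well above background on 2 of the 4 scap1 arrays, and its log2 fold change was -1.39 with normexp background correction. FLS1 lost its call without WT replicate 3 or 4 or scap1 replicate 1, 2 or 4 (-2.52 to -1.93 over the 8 fits that left out 1 array). CHS, the entry enzyme of the pathway, had -1.95 ± 0.48 and did not pass over all genes (adjusted p = 0.0512), but did with slide as a block (adjusted p = 0.000845). Slide medians were -1.69, -2.16 and -2.19, and the list passed with slide as a block (adjusted p = 0.00121) but not with the arrays of slide 1 alone (adjusted p = 0.053). Circadian clock genes had a median of -0.34 over 13 members, of which none passed singly, also adjusted over the list alone (camera, adjusted p = 0.0224, and adjusted p = 0.195 with an estimated correlation). Its slide medians were -0.49, -0.28 and -0.19, with an adjusted p of 0.0157 with slide as a block. Photosynthesis genes, with a median of -0.69 on the same arrays, were nearest to 0 on slide 1 (-0.24), where the clock list had its lowest median.

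Salicylic acid defence genes had a median of 0.29 over 16 members (camera in the upward direction, adjusted p = 0.0231, and adjusted p = 0.483 with an estimated correlation). Fry passed for either direction (adjusted p = 0.000104) and not for 1 direction (adjusted p = 0.0869). CBP60g (2.12 ± 0.31), a calmodulin-binding regulator of salicylic acid synthesis, FMO1 (1.96 ± 0.31), a monooxygenase of systemic resistance, and ICS1 (1.13 ± 0.26), the isochorismate synthase, rose, and NIMIN1 (-1.43 ± 0.29), which binds the regulator NPR1, fell. Adjusted over the list alone 6 rose and 1 fell. The call of the list was lost with slide as a block (adjusted p = 0.0994), with the replicate number as a block (adjusted p = 0.106), with the version of the feature extraction as a block (adjusted p = 0.0852) and without WT replicate 1 (adjusted p = 0.0548), WT replicate 2 (0.0866) or scap1 replicate 4 (0.0688). The slide medians were 0.60, 0.14 and 0.13. CBP60g and FMO1 kept their calls in all 8 fits that left out 1 array. ICS1 kept it only without WT replicate 4 (0.94 to 1.27 over the 8 fits) and NIMIN1 only without scap1 replicate 4 (-1.68 to -1.29). ICS1 also lost it with no filter (adjusted p = 0.0709) and NIMIN1 with median scaling (adjusted p = 0.0524). NIMIN1 was at -2.07 on slide 1 alone and -0.79 on slides 2 and 3. DOF transcription factor genes, the family of SCAP1, had a median of 0.31 over 20 members, none past the threshold over all genes or adjusted over the list alone (camera, adjusted p = 0.0389, and adjusted p = 0.643 with an estimated correlation). Fry did not pass for 1 direction (adjusted p = 0.268) or for either (adjusted p = 0.226). Camera's call held with slide as a block (adjusted p = 0.0157; slide medians 0.37, 0.48 and 0.30). It was lost with the version of the feature extraction as a block (adjusted p = 0.0754) and with the arrays of slide 1 alone (0.053). It was also lost without WT replicate 1 (adjusted p = 0.0548), WT replicate 2 (0.191), WT replicate 3 (0.0564) or scap1 replicate 4 (0.227), and among probes well above background on all 8 arrays (0.0631). On the same arrays as both lists the vascular markers had a median of 0.49 and the photosynthesis genes of -0.69.

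Cuticle and wax genes included 5 that fell of 28, also adjusted over the list alone, and none that rose. CYP77A6 and GPAT8, enzymes of cutin synthesis, changed by -3.15 ± 0.52 and -1.82 ± 0.35, the wax genes CER2 and KCS9 by -1.37 ± 0.22 and -0.96 ± 0.20, and MYB96, a regulator of wax synthesis, by -0.87 ± 0.20. CYP77A6 was well above background on 3 of the 4 scap1 arrays, and was at -1.76 with normexp background correction and -2.50 with slide 1 alone, where GPAT8 was at -1.23. With slides 2 and 3 alone the values were -3.80 and -2.41. GPAT8 lost its call without WT replicate 3 or 4 or scap1 replicate 1, 2 or 4 (-2.05 to -1.58 with 1 array left out). KCS9 lost it without WT replicate 1, 2 or 3 or scap1 replicate 1, 2 or 3 (-1.07 to -0.89) and with median scaling (adjusted p = 0.0946) or no filter (0.0582), and on slides 2 and 3 alone with slide as a block (-0.58, adjusted p = 0.0552). The list did not pass as a set (median -0.23, but 0.03 without WT replicate 1; camera, adjusted p = 0.0975, and adjusted p = 0.643 with an estimated correlation; fry in either direction, adjusted p = 0.000531). Slide medians were -0.50, 0.03 and -0.18, and the adjusted p with slide as a block was 0.0994. It passed without WT replicate 3 (adjusted p = 0.0419), WT replicate 4 (0.0365) or scap1 replicate 1 (0.030). Of 37 cell wall genes, PME6 and PME3, both pectin methylesterases, fell, and 2 rose and 3 fell adjusted over the list alone. PME3 had a log2 fold change of -2.15 ± 0.43. Its call was lost without WT replicate 1, 3 or 4 or scap1 replicate 1, 3 or 4 (-2.50 to -1.90 with 1 array left out), and with slide 1 alone (-1.13, adjusted p = 0.0785), against -3.18 with slides 2 and 3 alone. The cell wall median was 0.25 and its mean -0.01 (camera in the upward direction, adjusted p = 0.434, and adjusted p = 0.706 with an estimated correlation; fry in either direction, adjusted p = 0.00208). Slide medians were 0.42, 0.24 and 0.00 (adjusted p = 0.226 with slide as a block).

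Of 16 epidermis and trichome markers measured, ETC1, a repressor of trichome fate, fell (-1.69 ± 0.27, and -1.04 with normexp background correction). The trichome factor TTG2 was not well above background on any scap1 array and was at least 4.81-fold lower there (limma, adjusted p = 0.00108). Its fitted log2 fold change went from -3.89 to -1.20 with normexp background correction. The lipid transfer protein gene LTP2 rose (1.6 ± 0.33). Its call was lost without WT replicate 2, 3 or 4 or scap1 replicate 1, 2 or 3 (1.42 to 1.82 with 1 array left out). Adjusted over the list alone 2 rose and 4 fell (median -0.23; camera, adjusted p = 0.200, and adjusted p = 0.686 with an estimated correlation). Camera did not pass, but fry found change in either direction (adjusted p = 9.21e-06). Fry found change in 1 direction, down on balance, with slide as a block (adjusted p = 0.0310) and not without it (adjusted p = 0.0869). Slide medians were -0.38, -0.18 and -0.13, and camera's adjusted p with slide as a block was 0.200. Among 36 genes of starch, sugar and malate metabolism, GPT2, the plastid glucose 6-phosphate carrier, rose (1.95 ± 0.21) in every fit that left out 1 array. The starch branching enzyme SBE2.1 rose (1.53 ± 0.37) with a call that only the fit without WT replicate 3 kept (1.28 to 1.76 over these fits). That call was also lost after quantile normalization (adjusted p = 0.0503) and with no filter (0.0764). That list had a median of -0.36, with 2 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.200, and adjusted p = 0.706 with an estimated correlation; fry in either direction, adjusted p = 0.00304). Slide medians were -0.02, -0.58 and -0.70 (adjusted p = 0.200 with slide as a block), and the list passed without WT replicate 1 (adjusted p = 0.0497).

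Camera called none of the 3 lists of wounding, heat shock and glucosinolate genes, which leaf blending and enzyme digestion could also move. Fry for change in either direction did not pass for them without a block (adjusted p = 0.128, 0.510 and 0.370) and passed for each with slide as a block (adjusted p = 8.18e-05, 0.0325 and 0.00306). Of 31 wounding, jasmonate and touch genes the calmodulin-like gene TCH2 fell (-0.90 ± 0.22, adjusted p = 0.0498), a call lost without each of the 8 arrays in turn (-0.98 to -0.78) and absent adjusted over the list alone. It was also lost with median scaling, quantile normalization, no filter, the mean of its probes, the value table and slide 1 alone (-0.44), with adjusted p from 0.0509 to 0.104. The list had a median of 0.04, but -0.02 after quantile normalization, and a mean of 0.04 (camera in the downward direction, adjusted p = 0.929, and adjusted p = 0.975 with an estimated correlation). Slide medians were -0.11, -0.16 and 0.20 (adjusted p = 0.940 with slide as a block). None of the 8 heat shock genes passed, also adjusted over the list alone (median -0.33; camera, adjusted p = 0.641, and adjusted p = 0.885 with an estimated correlation). Slide medians were -0.27, -0.24 and -0.84, and the adjusted p with slide as a block was 0.200. None of 15 glucosinolate genes passed, also adjusted over the list alone (median 0.18; camera, adjusted p = 0.617, and adjusted p = 0.885 with an estimated correlation). Slide medians were 0.72, -0.05 and -0.52, and the adjusted p with slide as a block was 0.394. That list passed without WT replicate 4 (adjusted p = 0.0373).

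**Figure D3:**
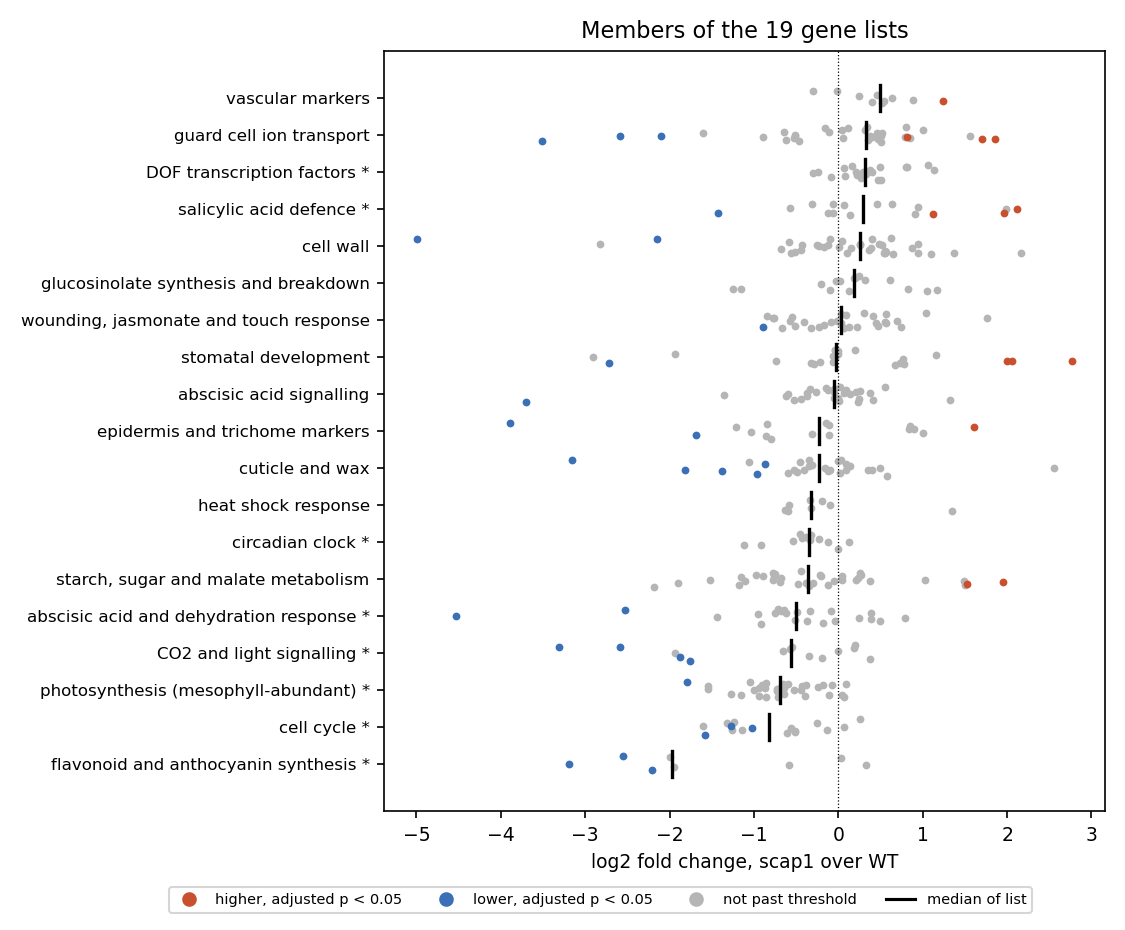
Log2 fold change of scap1 over WT (horizontal axis) of each measured member of the 19 gene lists (vertical axis), with red for genes higher and blue for genes lower at an adjusted p under 0.05, grey for the others, a bar for the median and an asterisk where camera with the preset correlation passed. The flavonoid list has the lowest median (-1.97) and the vascular list the highest (0.49), and TTG2, dim in scap1, is drawn at its fitted value.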

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

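Of the tests in this part, the count over splits of the arrays was planned before the result was seen, and the tests of marker genes, gene lists and detection were chosen only after it.

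In 5 of 182 groups of 4 arrays 1 array lay far from the other 3, by a gap past Dixon's 95% critical value. Chance flags about 1 in 20 groups, or 9.1 of 182 here. AT3G59710 in WT had a gap of 0.934 of its range, with replicate 3 at -6.36 and the others from -7.58 to -7.50. For AT5G50090 in WT the gap was 0.835, with replicate 2 at -5.26 and the others from -4.40 to -4.23. AT1G29660 in scap1 had 0.84, with replicate 1 at -4.60 and the others from -2.52 to -2.13. MYB60 in scap1 had 0.874, with replicate 4 at -0.90 and the others from 0.11 to 0.25. The 75th percentile of the WT arrays had 0.903, with replicate 2 at 1730 and the others from 1475 to 1500. Among probes with no single locus, which the comparison of genes leaves out, 114 of 3274 passed the threshold when each probe was tested singly, 33 higher and 81 lower in scap1.

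Chance could not be excluded for the count of genes by splits of the arrays. Of the 35 splits into 4 and 4, 2 gave at least 1172 genes: the real one and the split of slide 1 against slides 2 and 3, which gave 4667, several times the real count, and points to a structure of the samples by slide. The other 33 splits gave 0 genes, among them the 7 others that part all 4 replicate pairs as the real split does. With slide as a block the real split gave 5326 genes and the 11 other splits balanced on every slide gave 0, and these 12 splits are too few for a share under 0.05. For the lists, 4 of the 35 splits gave at least the real 8 lists, the highest other giving 10, and among the other splits that part all 4 pairs the highest gave 8, so that chance could not be excluded there either.

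The 9 genes of guard cell ion transport and signalling that passed lower (GORK, ALMT12, CAX1, BLUS1, CBC1, PHOT1, HT1, PYL2 and MYB60, with a median of -2.59) may reflect fewer guard cells in the scap1 preparations, a smaller amount of these mRNAs per cell, or RNA of other cells. The 7 genes taken as guard cell markers (SLAC1, KAT1, KAT2, FAMA, MPK12, TGG1 and TGG2) had a median of -0.467, with a 95% bootstrap interval over genes from -1.24 to 0.67. SLAC1, KAT1, KAT2, MPK12 and TGG1 lay between -1.61 and -0.35, while FAMA (0.67) and TGG2 (1.16) were higher in scap1. These genes may not all be particular to guard cells, and the interval holds no spread between arrays. The median of -2.59 comes from genes picked because they passed lower, so that a loss of guard cells can be neither excluded nor sized. More mesophyll RNA in scap1, which a density gradient was to remove from each preparation, would by itself raise the photosynthesis genes. Their median was instead -0.689 (-0.86 to -0.53 over genes) and lay between -1.41 and -0.24 on the slides. Lower levels within guard cells, which express these genes too, could hide such RNA, and camera lost the shift with an estimated correlation (adjusted p = 0.643). More mesophyll RNA in scap1 is thus not excluded. An effect of the genotype on these genes stays open as an untested hypothesis.

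The higher SPCH, MUTE and ERL1 could come from more dividing precursor cells in the scap1 preparations. The cell cycle genes instead had a median of -0.821 (-1.26 to -0.41 over genes), and between -1.04 and -0.48 on the slides. That interval holds no spread between arrays, and camera lost the shift with an estimated correlation (adjusted p = 0.155). More dividing precursor cells are thus not excluded. Signals near the detection limit could also play a part. Of the 24 values of these genes, 23 were well above background. The filter fixed part of that count, since only genes well above background on enough arrays were tested. In WT the means of SPCH, MUTE and ERL1 were -5.12, -5.61 and -4.10. The lowest spot signals well above background on the WT arrays ran from -6.96 to -6.30. With normexp background correction SPCH fell to 1.74 and MUTE to 0.97. The count therefore cannot decide on signals near the detection limit, which are not excluded. More precursor cells of any kind could also raise other precursor genes, but the 6 other members of the list known from precursors did not rise as a set. Their median was -0.0335 (-2.42 to 0.772), with EPF1 at -2.91 and SDD1 at -1.93, EPF2 at -0.06 and POLAR at -0.01, and TMM at 0.78 and HDG2 at 0.77, against 1.99 for the smallest of the 3 rises. These 6 genes may mark other stages or cells than SPCH, MUTE and ERL1, and the interval holds no spread between arrays. They therefore cannot decide on a gain of precursor cells, which stays open, as does an effect of the genotype, untested.

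The lower photosynthesis genes may come from more mesophyll RNA in the WT preparations, although the protocol removed mesophyll cells on a density gradient, or from lower levels within guard cells of the mutant, which express these genes too. The 2 cannot be told apart here: that 30 of the 33 members lay below 0, with an SD of 0.47 between members, restates the pattern and decides nothing. Of genes known as abundant in mesophyll, RBCS1A was at 3.99 ± 0.97 in WT and 3.40 ± 0.54 in scap1, and LHCB1.3 at 4.84 ± 0.67 and 4.12 ± 0.16 (SD, n = 4). No list told mesophyll from guard cells. The genotype stays among the open explanations, untested.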

How the results depend on the processing

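The arrays of slide 1 alone, those of slides 2 and 3 alone, and the estimated inter-gene correlation with slide as a block were chosen only after the data were seen. Signals near background limit the low genes, since below it a change has only a bound, and the main model recovered few simulated 2-fold changes (0.2%). No named gene reversed: of 1390 values of named genes under the alternatives, 1231 kept their direction and their side of the threshold and 159 missed the threshold. The groups of these genes did not overlap, so that leaving out arrays or fitting a block could not reverse a sign. For those settings the lack of reversals is no added support. Of the list results 368 kept both, of the gene counts 35 lay within 1.5-fold of the main count, and of the SCAP1 results 16 kept both. For the results below the cause was not tested, except where a stricter threshold gave it. Leaving out 1 array also left its slide unbalanced between the groups, and those fits held no term for slide. Fewer arrays and differences between slides cannot be told apart there.

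Blocks raised the count of genes past the threshold from 1172 to 5326 with slide (2692 higher and 2634 lower), to 4522 with the replicate block (2319 and 2203) and to 4184 with the version of the feature extraction (2003 and 2181). SCAP1, at 1.09, passed with each of the 3 (adjusted p = 0.0175, 0.0335 and 0.028). Salicylic acid defence, at 0.295, missed the threshold with each (0.0994, 0.106 and 0.0852). DOF genes, at 0.313, missed it with the version (0.0754), and vascular markers, at 0.488, passed with the replicate block (0.026). The replicate block changed no other call of a list or named gene.

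At an adjusted p under 0.01 the count was 302 (120 higher and 182 lower). Median scaling gave 826 higher genes and no filter 305. The median of stomatal development turned to 0.115 after quantile normalization and to 0.168 after median scaling, that of abscisic acid signalling to 0.147 after median scaling, and that of the wounding list to -0.0209 after quantile normalization, none past the threshold. Vascular markers passed with no filter (0.463, adjusted p = 0.0451) and with the mean of all probes (0.488, adjusted p = 0.0297), and DOF genes missed the threshold with the filter on all 8 arrays (0.294, adjusted p = 0.0631).

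With an estimated correlation no list passed: carbon dioxide and light signalling (-0.562, adjusted p = 0.155, and 0.421 with slide as a block), abscisic acid and dehydration response (-0.498, 0.170 and 0.515), photosynthesis (-0.689, 0.643 and 0.658) and salicylic acid defence (0.295, 0.483 and 0.658). The same held for the circadian clock (-0.342, 0.195 and 0.410), flavonoid synthesis (-1.97, 0.145 and 0.410), cell cycle (-0.821, 0.155 and 0.410) and DOF genes (0.313, 0.643 and 0.658).

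Slide 1 alone, with 2 arrays per group, gave 4401 genes (1765 higher and 2636 lower), and SCAP1 passed at 1.53 (adjusted p = 0.0225). There the cell wall list passed (0.419, adjusted p = 0.0435), the wounding list turned to -0.115, and the threshold was missed by carbon dioxide and light signalling (-0.495, adjusted p = 0.0699), DOF genes (0.370, 0.053), abscisic acid and dehydration response (-0.469, 0.053), flavonoid synthesis (-1.69, 0.053), photosynthesis (-0.245, 0.105) and salicylic acid defence (0.598, 0.053). Slides 2 and 3 alone gave 7891 genes (4180 higher and 3711 lower), SCAP1 passed at 0.645 (adjusted p = 0.043) and starch, sugar and malate metabolism at -0.603 (0.00531), while the circadian clock (-0.196, 0.0967) and salicylic acid defence (0.215, 0.532) missed the threshold. The medians of abscisic acid signalling (0.131), glucosinolate genes (-0.249), stomatal development (0.467) and the wounding list (-0.0654) reversed there without passing.

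With 1 array left out the count ran from 536 (without scap1 replicate 1) to 906 (without WT replicate 1), with 199 to 384 higher and 335 to 522 lower. It was under the main count by more than 1.5-fold without WT replicates 2 (748), 3 (560) and 4 (732) and scap1 replicates 1, 2 (680) and 4 (748). SCAP1 ran from 0.729 to 1.54 and passed in none of the 8 fits. List medians that changed sign ran from -0.0419 to 0.126 for stomatal development (above 0 without WT replicates 1 and 2 and scap1 replicates 1, 2 and 4) and from -0.191 to 0.0381 for abscisic acid signalling (above 0 without scap1 replicates 1 and 2). They ran from -0.279 to 0.0285 for cuticle and wax (above 0 without WT replicate 1) and from -0.116 to 0.148 for the wounding list (below 0 without WT replicate 2 and scap1 replicate 4). They also ran from -0.159 to 0.542 for glucosinolate genes (below 0 without WT replicate 2) and from -0.832 to 0.0141 for heat shock (above 0 without WT replicate 3). Medians whose call changed ran from -0.476 to -0.194 for starch, sugar and malate metabolism (past the threshold without WT replicate 1) and from 0.238 to 0.712 for vascular markers (past it without WT replicate 4 and scap1 replicate 2). They ran from 0.238 to 0.482 for salicylic acid defence (not past it without WT replicates 1 and 2 and scap1 replicate 4) and from 0.132 to 0.495 for DOF genes (not past it without WT replicates 1, 2 and 3 and scap1 replicate 4). Cuticle and wax passed without WT replicates 3 and 4 and scap1 replicate 1, and glucosinolate genes passed without WT replicate 4. The other 9 lists kept their direction and their side of the threshold in all 8 fits.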

Other observations

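Of the tests in this part, that of the chromosome segment around SCAP1 was chosen only after the result was seen, and the 4 gene lists were chosen after single genes had been seen, with their tests written before the other members were looked at.

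Some genes with large changes are known from other tissues. TIP3;1, a tonoplast aquaporin of seeds, was lower in scap1 (log2 fold change -3.84; limma, adjusted p = 0.00257), and RWP1, a feruloyl transferase of suberin, and IRX12, a laccase, were higher (3.58 and 3.72; adjusted p = 0.00139 and 0.000971). These 3 genes were chosen after their values were seen. Of other seed maturation genes, M10, a late embryogenesis abundant gene, was lower (-2.90, adjusted p = 0.0168), SESA2, a seed storage albumin, was not well above background on any scap1 array and at least 1.87-fold lower there (adjusted p = 0.00691), and TIP3;2 was higher (1.49, adjusted p = 0.0312). JAL34, a jacalin-related lectin, was higher (1.84, adjusted p = 0.0247).

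A hypothesis that seed maturation genes fall together with FUS3 was not settled: the 14 measured other members of 29 had a median of 0.068 (95% bootstrap interval -0.67 to 0.33; camera, adjusted p = 0.83, and adjusted p = 0.876 with an estimated correlation). A hypothesis that suberin genes rise with RWP1 and IRX12 was argued against by the 13 measured other members of 20, with a median of -0.0018 (-0.49 to 0.17; adjusted p = 0.597, and 0.728 with an estimated correlation). For genes of endoplasmic reticulum bodies, where PYK10 is abundant, the 5 measured other members of 10 had a median of 1.001 (0.42 to 1.84), and slide medians of 1.28, 0.98 and 1.19. Camera called that list higher with the preset correlation (adjusted p = 0.00699, and 0.0223 with slide as a block) but not with an estimated one (adjusted p = 0.334), so that a shared rise may exist and is not settled. For the thalianol and marneral clusters only 2 of 7 other members were measured, with a median of 0.67 (-0.35 to 1.69; adjusted p = 0.620, and 0.728 with an estimated correlation), too few to tell.

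A segment of another accession linked to the mutation could make genes near SCAP1 differ. Of 781 genes tested within 2.5 Mb of SCAP1, 40 (5.12%) passed, against 1129 of 19568 elsewhere (5.77%), a ratio of 0.888 (95% interval 0.653 to 1.21), which argues against a segment that raises the share 2-fold within that distance.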
